A study of Mus musculus with 3 samples.

How the data were processed

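Stromal cells were obtained, per the labels' protocols, by collagenase digestion of mouse mesenteric lymph nodes, magnetic removal of CD45-bearing cells and sorting of CD45-negative, CD24-negative cells by gp38 and CD31. The labels give a sorted purity below full purity as a mean over subsets and do not say how many mice or sorts went into each RNA. Per the labels' protocols, total RNA was amplified in a single round to aminoallyl-modified cRNA, and coupled to Alexa Fluor 555. Per the file headers, the arrays are single-colour Agilent mouse arrays. The 3 populations (FRC, LEC and BEC) had 1 array each. Per the file headers, all 3 arrays lay on 1 slide, so slide and population are not confounded, but no array of any population is repeated.

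The deposited scanner files hold intensity values for 43379 non-control spots, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, the processed intensity is background-subtracted and detrended within the array, with low values replaced by surrogates and no scaling between arrays. The 75th percentile of the processed intensity was 387 on the FRC array, 268 on the LEC array and 361 on the BEC array, and the lowest intensity well above background was 19.1, 14.6 and 17.4. No spot was saturated. Per the file headers, the slope of log signal on log concentration over spike-in controls was 0.821 for FRC, 1.00 for LEC and 0.919 for BEC, so equal differences in RNA need not give equal log2 differences on every array. The deposited series matrix also holds linear intensity values by the authors. Its sorted columns differ by at most 0.943, its lowest value is 15 in each column, and the median of every column is 40.2. Against the scanner values its log2 values had a correlation of 0.99998 across probes above that floor on each array, so its scale is linear and uncentred with quantile-normalized columns, and a single-colour intensity has no direction to settle. Which program made it is not given in the sources used here.

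Spots that the scanner software marked as outliers were left out, which removed 18 probes, and replicate spots of a probe were averaged, leaving 41156 probes. Each value is log2 of the processed intensity minus the 75th percentile of the array. A probe counted as well above background if most of its kept spots carried that mark of the scanner software. The files' gene names were updated through the RefSeq accession with a GRCm38.p6 table, used for names only, which matched 18208 of the gene names. The accession matched for 26681 probes, and 2235 of 28076 names changed. A gene stands for its probe with the highest mean over the 3 arrays, and 8738 genes had several probes. Probe positions are those in the files, on mouse build mm9 per the file headers, and no annotation of exons or UTRs on that build was used here.

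A gene was compared if any of its probes was well above background on either array, and was called higher at 4-fold. Where no probe was well above background on the dimmer array, that array was set at the higher of the probe's own value and the lowest value well above background there, and the fold is given as at least that size. The named genes were, per comparison and direction, the 8 largest differences measured on both arrays and the 4 largest bounds (in no order), both among official-style symbols, plus members of 32 gene lists. A list's median log2 difference, with bounds in place, was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. A gene whose own probe was dim on the dimmer array while another of its probes was well above background kept its measured difference. These choices were made before the data were examined, apart from the number of bins and a further condition that the gene's own probe be well above background on the brighter array for a call. In all, 96 list medians were computed. A further 6 lists were chosen after the data had been seen.

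The 245 probes spotted 10 times gave a median SD between spots of 0.05 to 0.06 on the log2 scale, which covers spot error only and not differences between animals, sorts or amplifications. The number of arrays limits the precision. Across 15641 genes well above background on all arrays, the correlation was 0.876 for LEC and FRC, 0.837 for BEC and FRC and 0.929 for LEC and BEC. These are across genes, which are not independent replicates. The comparison and list steps were run on simulated data as a check of the steps. The simulated noise was small against the 4-fold threshold, and detection was the same on all simulated arrays. The calls that follow were therefore set by the design, give no rate of false calls and do not test the bounds. In a simulated LEC minus FRC comparison of 15620 genes with an SD of 0.15, all 100 genes shifted 8-fold were called, none of 100 shifted 2-fold and none of 15420 unshifted genes were called, and 4.00% of 200 unshifted lists fell outside the middle 95%.

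The alternatives planned were quantile normalization, scaling to the median, normexp background correction with an offset of 50 on the mean and background intensity, the series matrix values, no filter on dim probes, a filter requiring both arrays, the mean of all probes of a gene, thresholds of 2-fold and 8-fold, and leaving out saturated probes. The setting with no filter on dim probes also used no lower bounds and no condition on the brighter array. Normexp moved the median difference of all genes by 0.10 for LEC minus FRC and 0.11 for LEC minus BEC. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1, were used.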

Results

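Gene expression was measured in 3 stromal cell populations sorted from the mesenteric lymph node of mice, the node that drains the intestine. Fibroblastic reticular cells (FRC; gp38 positive, CD31 negative) build the fibre network of the T cell area, lymphatic endothelial cells (LEC; gp38 and CD31 positive) line the lymph sinuses, and blood endothelial cells (BEC; gp38 negative, CD31 positive) line the blood vessels, including the high endothelial venules through which lymphocytes enter. Each population was hybridised to 1 single-colour whole-genome array, 3 arrays in all, so there are no replicates, no difference below has a replicate check, and no statistical test of a difference between populations was made. Values are log2 signals relative to the 75th percentile of the same array, and a fold is the ratio between 2 arrays for the same probe. Of 41156 probes, 60.5% were well above background on the FRC array, 59.7% on the LEC array and 60.1% on the BEC array. A total of 15641 genes had such a probe on all 3 arrays, 836 on the FRC array alone, 328 on the LEC array alone and 718 on the BEC array alone.

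The genes behind the sort gates were read first. Pecam1, which encodes CD31, was at -4.06 in FRC, 2.33 in LEC and 4.02 in BEC, and Pdpn, which encodes gp38, was at -0.83, -1.19 and -3.81. Cd24a and Ptprc, whose products CD24 and CD45 were gated out, were higher in BEC than in FRC, by 4.86-fold and 6.04-fold. In LEC against FRC the factors were 3.46 and 1.73. Of the 4 Ptprc probes, only the brightest was well above background on the FRC or BEC array. Over the 4 gate genes the median log2 difference was 1.29 for LEC minus FRC, 2.44 for BEC minus FRC and -1.09 for LEC minus BEC.

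The comparison of LEC with FRC asks how the lymphatic lining differs from the fibroblastic network. Most genes of the lymphatic and shared endothelial lists were at least 4-fold higher in LEC, and 11 of 18 FRC markers and 21 of 39 extracellular matrix genes at least 4-fold higher in FRC. Tbx1, a transcription factor of lymphatic development, was 229-fold higher in LEC. Lyve1, a hyaluronan receptor of lymphatic endothelium, was 224-fold higher and Mmrn1, a secreted multimerin, 218-fold. Pdgfra, the platelet-derived growth factor receptor of fibroblasts, was 64.1-fold higher in FRC, and Penk, which encodes the enkephalin precursor, 79.2-fold.

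Of 18440 genes compared, 902 were at least 4-fold higher in LEC and 1094 at least 4-fold higher in FRC. The largest differences measured on both arrays further included Stab1, a scavenger receptor of sinusoidal endothelium (208-fold), the tight junction gene Cldn11 (203-fold), the endothelial receptor tyrosine kinase Tie1 (170.3-fold), Ackr4, an atypical receptor that takes up CCL19 and CCL21 (150.1-fold), and the transporter-family gene Mfsd4a (137-fold), all higher in LEC. Tie1 and Mfsd4a were near the lowest FRC signal well above background, at -4.04 and -4.10. The Lyve1 probe lay on chromosome 7 at 117994171 to 117994230 and the Tbx1 probe on chromosome 16 at 18581816 to 18581875. Ccl20, a chemokine for CCR6-bearing cells, was at least 283-fold higher in LEC, the lectin-like receptor gene Klrb1f at least 389.8-fold, the transcription factor gene Gata2 at least 189-fold and endothelial nitric oxide synthase, Nos3, at least 167-fold. None of these 4 was well above background on the FRC array.

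On the FRC side, Pcolce2, which enhances procollagen processing, was 82.5-fold higher, the leucine-rich repeat gene Lrrc17 70.2-fold, the glutaminyl cyclase gene Qpct 67.5-fold, Srpx 63.0-fold and the ephrin receptor gene Epha3 60.7-fold. Nudt6 was 83.0-fold higher through its brightest probe, but its other 2 probes well above background did not follow, with LEC minus FRC differences of 0.51 and -0.06. The Pcolce2 probe lay on chromosome 9 at 95595436 to 95595495 and the Pdgfra probe on chromosome 5 at 75593888 to 75593947. Alkal2, a ligand of the ALK receptor, was at least 67.5-fold higher in FRC, the interferon-inducible gene Ifi205 at least 52.6-fold, the aminopeptidase gene Xpnpep2 at least 51.2-fold and the acute-phase gene Saa3 at least 44.5-fold.

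Among the marker lists, 17 of 20 lymphatic genes were at least 4-fold higher in LEC, with a median log2 difference of 6.40, above all 10000 random lists matched on expression. Prox1, the transcription factor that sets lymphatic identity, was 137-fold higher, and Marco, a scavenger receptor of medullary sinus endothelium, 126-fold. Ccl21a, the CCR7 ligand that guides T cells and dendritic cells, went the other way and was 6.25-fold higher in FRC. The list of genes shared by endothelia had 18 of 22 members higher in LEC (median 5.09), among them Cdh5, the endothelial cadherin (41.6-fold), and Cldn5 (117-fold). Blood endothelial markers had 16 of 22 members higher in LEC than in FRC and 3 lower (median 2.90), and high endothelial venule genes 5 of 16 and 1 lower (median 1.20). Of 18 FRC markers, 11 were higher in FRC and 1 in LEC (median -3.93). Of these 18, 8 are also in another list, such as Col1a1 and Col3a1 in the matrix list. Ccl19 was 13.4-fold and Cxcl13, the B cell follicle chemokine, 19.3-fold higher in FRC, whereas Thy1 was 4.74-fold higher in LEC. Extracellular matrix genes had 21 of 39 members higher in FRC (median -2.71), such as Col1a1 (38.7-fold) and Lum (46.3-fold). The 2 matrix genes higher in LEC were Tnc, tenascin C (17.7-fold), and Col12a1 (5.80-fold).

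Where another probe of a gene was well above background, it went the same way for 270 of 286 genes called higher in LEC and for 332 of 357 called higher in FRC. Sizes differed more between probes: on the log2 scale and toward the same side, other probes read 5.99 for Stab1, 4.36 to 6.63 for Mfsd4a, 6.58 for Klrb1f, 4.92 for Pdgfra, 2.01 to 4.38 for Epha3, 5.34 to 5.66 for Prox1, 6.52 for Cdh5 and 1.66 for Thy1. Under normexp background correction the counts were 550 and 636.

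The comparison of BEC with FRC asks how the vascular lining differs from the fibroblastic network, and it gave the largest counts. Of the blood endothelial markers, 19 of 22 were at least 4-fold higher in BEC, and of the extracellular matrix genes 23 of 39 were at least 4-fold higher in FRC. Rbp7, a retinol-binding protein gene, was 795-fold higher in BEC. Emcn, the endothelial sialomucin endomucin, was 361-fold higher and Sox17, a transcription factor of arterial endothelium, 317-fold. Sfrp2, a secreted Wnt antagonist, was 330.5-fold higher in FRC, and F3, tissue factor, 384-fold.

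Of 18830 genes compared, 1240 were at least 4-fold higher in BEC and 1426 at least 4-fold higher in FRC. Scgb3a1, a secretoglobin gene, was 442-fold higher in BEC, Tie1 371-fold, the C-type lectin-domain gene Cd93 339-fold, Depp1 275-fold and Pecam1 272-fold. On the FRC array Scgb3a1, Tie1 and Pecam1 were at -4.11, -4.04 and -4.06. The 75th percentile there was 20.2 times the lowest signal well above background, so these folds rest on FRC signals near that floor. The Rbp7 probe lay on chromosome 4 at 148823823 to 148823882 and the Emcn probe on chromosome 3 at 137093811 to 137093870. Lower bounds were given for Exoc3l2 (at least 416-fold), the prion-like gene Prnd (at least 401-fold), the capillary carbonic anhydrase gene Car4 (at least 365-fold) and the endothelial adhesion receptor gene Adgrl4 (at least 348-fold), which were not well above background in FRC.

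On the FRC side, Pcolce2 was 415-fold higher, Vit, which encodes the matrix protein vitrin, 333-fold, the stromelysin gene Mmp3 262-fold, Pdgfra 249.6-fold, the tetranectin gene Clec3b 245-fold and Rab7b 215-fold. Not well above background in BEC were the BMP antagonists Chrdl1 and Grem1, at least 269-fold and 187-fold higher in FRC, the microfibril gene Mfap5, at least 263-fold, and the Wnt antagonist Sfrp4, at least 196-fold. F3 and Mmp3 were near the lowest BEC signal well above background, at -4.23 and -4.12. The Sfrp2 probe lay on chromosome 3 at 83577864 to 83577923.

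Blood endothelial markers had 19 of 22 members at least 4-fold higher in BEC (median 6.24, above all 10000 random lists), among them Flt1, a VEGF receptor (180.5-fold), and Vwf, von Willebrand factor (106-fold). The remaining 3 were Cd34 (0.55), Nrp1 (-0.03) and Apln (1.56, log2). High endothelial venule genes had 12 of 16 higher in BEC (median 3.14). Glycam1, a sulphated mucin ligand of L-selectin, was 98.5-fold higher, Fut7, the fucosyltransferase that builds such ligands, 116-fold, and Ackr1, an atypical chemokine receptor of venules, 15.6-fold. The shared endothelial list had 20 of 22 higher in BEC (median 6.22). Of 20 lymphatic markers, 13 were also at least 4-fold higher in BEC than in FRC (median 2.74), Lyve1 by 16.3-fold and Prox1 by 8.27-fold, while Maf was 10.2-fold higher in FRC. FRC markers had 11 of 18 higher in FRC (median -4.03). The single FRC-list gene higher in BEC was Ch25h, cholesterol 25-hydroxylase (6.67-fold). Ch25h is also in the high endothelial venule list and is counted there as well. Matrix genes had 23 of 39 higher in FRC (median -3.21), and the 3 higher in BEC were Hspg2 (6.36-fold), Lama5 (6.00-fold) and Col4a2 (4.64-fold).

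Other probes went the same way for 349 of 382 genes called higher in BEC and 435 of 481 called higher in FRC. Toward the same side and on the log2 scale, they read 3.35 for Pecam1, against 8.08 for its brightest probe, 5.82 for Cd93, 2.96 to 6.99 for Sox17, 4.23 for Vit, 5.06 for Pdgfra, 5.16 to 8.92 for Chrdl1, 9.22 for F3, 1.02 to 7.85 for Flt1, 1.70 for Lyve1, 1.07 to 3.48 for Maf and 3.02 for Col4a2. Under normexp the counts were 740 and 854.

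**Figure D1:**
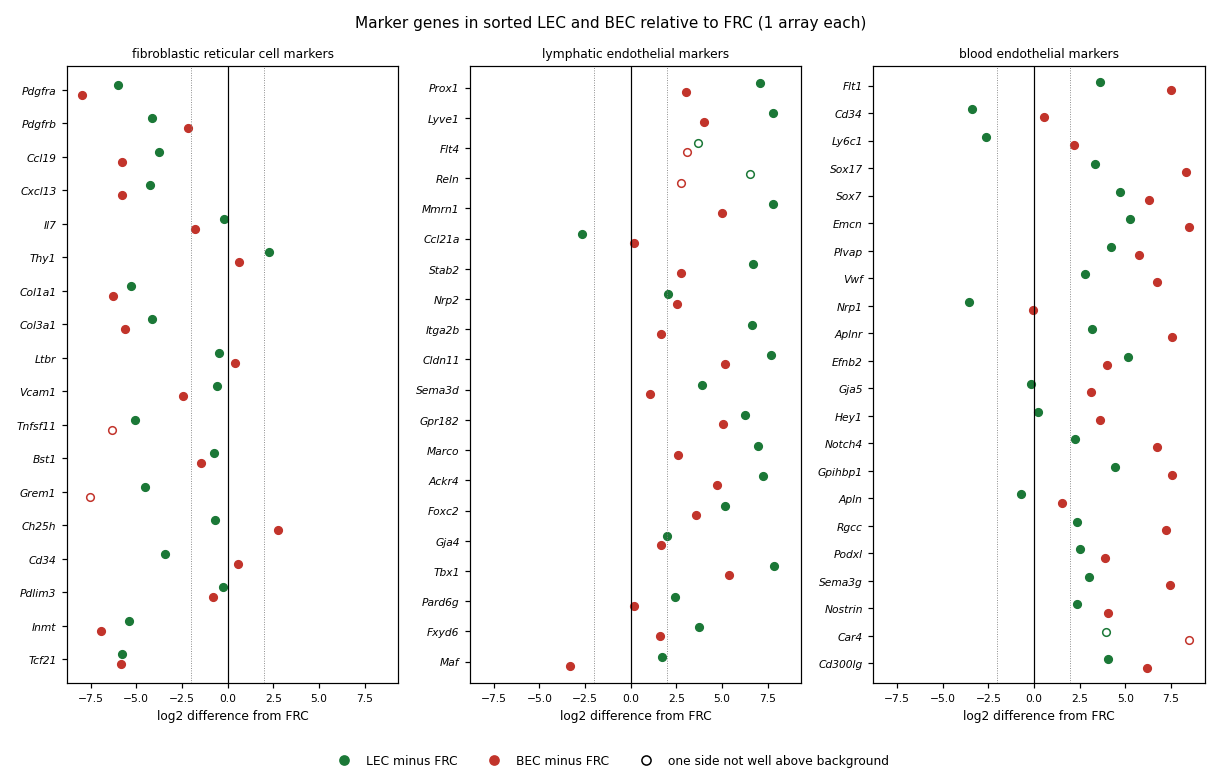
Log2 difference of LEC (green) and BEC (red) from FRC for the fibroblastic reticular, lymphatic and blood endothelial marker lists, 1 array per population, with dotted lines at 4-fold and open points where a side was not well above background. Most FRC markers lie left of 0 for both endothelia, and most lymphatic markers lie farther right for LEC than for BEC, for example Lyve1 at 7.81 and 4.02.

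The comparison of LEC with BEC sets the 2 endothelia against each other and gave the smallest counts. Of the lymphatic markers, 14 of 20 were at least 4-fold higher in LEC, and of the blood endothelial markers 17 of 22 were at least 4-fold higher in BEC. Bmp2, a bone morphogenetic protein gene, was 92.6-fold higher in LEC and Bmp8a 86.7-fold. Mycl, a Myc family transcription factor gene, was 160.5-fold higher in BEC, and Pltp, phospholipid transfer protein, 56.4-fold.

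Of 18322 genes compared, 622 were at least 4-fold higher in LEC and 620 at least 4-fold higher in BEC. Coch, which encodes the matrix protein cochlin, was 66.4-fold higher in LEC, Ccl20 64.8-fold, the transporter gene Abca13 59.2-fold, the glutamate receptor gene Gria3 50.6-fold, Maf 33.6-fold and Npl, a sialic acid lyase gene, 32.4-fold. The Bmp2 probe lay on chromosome 2 at 133386981 to 133387040. Mmp9, a gelatinase gene, was at least 142-fold higher in LEC, the homeobox gene Dbx2 at least 33.9-fold, the actin-bundling gene Fscn1 at least 30.9-fold and the endocytic receptor gene Lrp2 at least 26.2-fold, none of them well above background in BEC.

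On the BEC side, Scgb3a1 was 61.6-fold higher, Exoc3l2 42.8-fold, Prdm1, a transcriptional repressor gene, 41.5-fold, the LIM homeobox gene Lhx6 36.5-fold and the 12-lipoxygenase gene Alox12 33.7-fold. Mypn was 198-fold higher in BEC through its brightest probe, at 4.67 against -2.96, whereas its other probe read -4.12 in BEC and -3.81 in LEC. The other Lhx6 probe was 0.49 (log2) higher in BEC. The Mycl probe lay on chromosome 4 at 122679548 to 122679607. Bounds were given for the germ cell helicase gene Ddx4 (at least 75.8-fold), Cstl1 (at least 43.0-fold), the POU-domain gene Pou3f4 (at least 35.7-fold) and Nlrp9a (at least 30.2-fold), which were not well above background in LEC.

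The lymphatic markers had a median of 2.48, and those higher in LEC included Itga2b (31.4-fold), Marco (21.1-fold) and Prox1 (16.5-fold), while Ccl21a was 6.97-fold higher in BEC. Flt4, the VEGF-C receptor gene, differed by 0.59 (log2). None of the blood endothelial markers was at least 4-fold higher in LEC (median -3.47), and those higher in BEC included Sox17 (31.6-fold) and Rgcc (29.0-fold). High endothelial venule genes had 6 of 16 higher in BEC (median -1.81), and shared endothelial genes 2 of 22, Esam and Clec14a (median -0.85). FRC markers had 2 members higher in LEC, Ccl19 and Grem1, and 2 higher in BEC, Cd34 and Ch25h (median 1.39). Cd34 is also in the blood endothelial list, and Ch25h in the high endothelial venule list. Matrix genes split: 7 were higher in LEC, such as Postn (16.8-fold) and Col12a1 (15.1-fold), and 5 in BEC, such as Col15a1 (7.39-fold) and Col4a2 (5.13-fold), with a median of 0.90.

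Other probes went the same way for 185 of 216 genes called higher in LEC and 158 of 179 called higher in BEC. They read 2.99 to 5.83 for Gria3, 2.09 to 5.06 for Maf, 2.77 to 3.15 for Prox1, 2.36 to 4.39 for Sox17 and 3.59 for Col15a1, on the log2 scale and toward the same side. Under normexp the counts were 287 and 324, and with no filter on dim probes the LEC count was 1019.

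The series title concerns dietary lipids in the mesenteric node, so lists of lipid genes were read over all 3 populations. Fatty acid uptake, binding and lipoprotein receptor genes had 8 of 24 members higher in LEC than in FRC and 3 lower (median 0.71, percentile 99.98 among random lists), and 12 of 26 higher in BEC than in FRC and 4 lower (median 0.85, percentile 99.99, or 1.28 without the members given as bounds). On the same arrays, 6 of 12 adipocyte markers were at least 4-fold higher in BEC than in FRC and 2 lower (median 1.64, percentile 99.99), and 3 of 12 were higher in LEC than in FRC and 2 lower. Of the 13 adipocyte markers on the array, 4 are also in another list. Cd36, a fatty acid translocase, was 83.6-fold higher in LEC and 94.4-fold higher in BEC, and Fabp4, a fatty acid-binding protein of capillary endothelium, 11.2-fold and 31.8-fold. Gpihbp1, which carries lipoprotein lipase to the vessel lumen, was 187-fold higher in BEC, while the lipase gene itself, Lpl, was higher in FRC by 9.88-fold over LEC and 10.6-fold over BEC. Lrp1 was likewise higher in FRC, by 26.4-fold and 31.8-fold. Between the endothelia the median of the uptake list was 0.06 (0.02 to 0.13 over the scalings). Msr1, the class A scavenger receptor gene (26.7-fold), and Stab2 (15.4-fold) were higher in LEC, and Scarb1, the HDL receptor gene, was 16.6-fold higher in BEC.

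**Figure D2:**
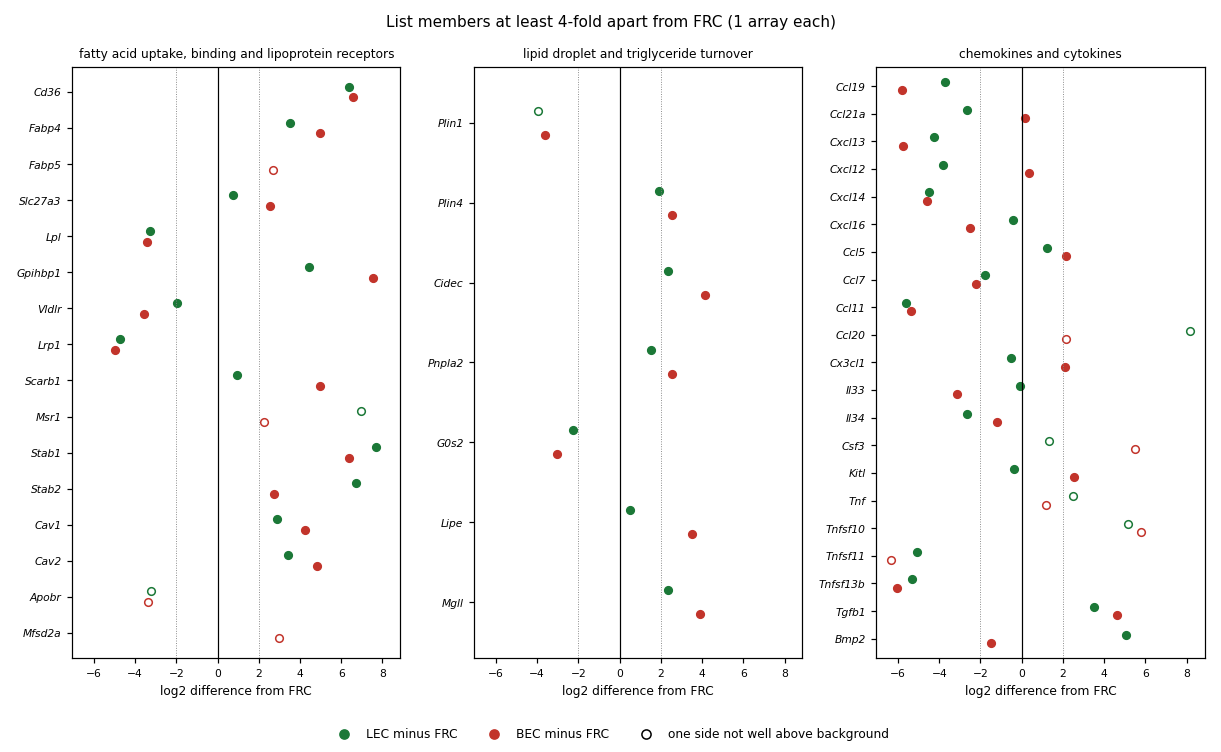
Log2 difference of LEC (green) and BEC (red) from FRC for members at least 4-fold apart from FRC in either endothelium, in the lists of fatty acid uptake, lipid droplets, and chemokines and cytokines, 1 array per population, with open points where a side was not well above background. Cd36 lies at 6.39 and 6.56, and Cxcl13 at -4.27 and -5.78.

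Lipid droplet and triglyceride genes had medians of -0.52 (LEC minus FRC), -0.17 (BEC minus FRC) and -0.14 (LEC minus BEC), with 2 of 25 members at least 4-fold higher in LEC than in FRC and 2 lower, and 5 of 25 higher in BEC than in FRC and 2 lower. The BEC minus FRC mean was 0.12, opposite in sign to the median. The first median ran from -0.55 to -0.11 over the scalings, the latter with normexp. That value lies inside the random range of the main scaling, -0.33 to 0.41. Mgll, monoglyceride lipase, was 5.12-fold higher in LEC than in FRC and differed by 3.91 (log2) for BEC minus FRC, and Lipe, hormone-sensitive lipase and also an adipocyte marker, 11.4-fold higher in BEC than in FRC. G0s2, an inhibitor of the triglyceride lipase, was 4.80-fold and 8.21-fold higher in FRC. Of the fatty acid oxidation genes, 0 of 26 reached 4-fold between LEC and FRC and 2 of 26 between BEC and FRC, Cpt1c and Ppara, both higher in FRC, with medians of -0.14, -0.11 (-0.20 to -0.07 over the scalings) and -0.00404 for LEC minus BEC. Fatty acid synthesis genes had medians of 0.05 (0.02 to 0.10 over the scalings), 0.10 and -0.04, with 4 of 24 members higher in LEC and 4 of 24 in BEC than in FRC. Thrsp, a lipogenic regulator gene, was 106-fold higher in BEC than in FRC, and Pparg, the adipogenic nuclear receptor gene and also an adipocyte marker, 5.81-fold higher in LEC and 5.87-fold higher in BEC.

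Cholesterol synthesis genes had a median LEC minus BEC difference of 0.48 (percentile 99.99), but only 1 of 24, Hsd17b7, reached 4-fold (5.53-fold). Their medians against FRC were -0.06 for LEC (-0.09 to -0.00672 over the scalings) and -0.40 for BEC. Cholesterol efflux and oxysterol genes had medians of -0.65, 0.19 and -0.05 for LEC minus FRC, BEC minus FRC and LEC minus BEC. The first was -0.19 with normexp, inside the random range of the main scaling, -0.39 to 0.43. Their calls were split, with 2 of 19 higher in LEC than in FRC and 3 lower, and 4 of 19 higher in BEC than in FRC and 4 lower. Abcg1, a cholesterol exporter gene, was 5.88-fold and 22.9-fold higher in LEC and BEC than in FRC, and Ch25h was 10.6-fold higher in BEC than in LEC. The LEC minus BEC medians of the lipid droplet, fatty acid oxidation, fatty acid synthesis and efflux lists took both signs across the scalings tried.

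Lists of lipid mediator genes had lower medians in both endothelia than in FRC. In the prostaglandin and leukotriene list, 6 of 17 genes were higher in FRC than in LEC and 1 lower (median -0.81), and 9 of 17 higher in FRC than in BEC and 2 lower (median -2.32). Both FRC counts include Ptgir, whose other probe read 0.51 and 0.44 (log2) higher in LEC and BEC. Ptger3 differed by 3.54 (log2) between BEC and FRC through its brightest probe and by 0.04 through another. Ptgis, prostacyclin synthase, was 41.0-fold and 53.7-fold higher in FRC, and Ptges, prostaglandin E synthase, 10.3-fold and 37.7-fold. Ltc4s, leukotriene C4 synthase, was 7.08-fold higher in LEC than in FRC, and the LEC minus BEC median was 0.84 (0.56 with the lowest of the scalings). Sphingosine-1-phosphate and lysophospholipid genes had medians of -1.54, -0.47 and 0.13, the last running from 0.06 to 0.35 over the scalings against a main-scaling random range of -0.46 to 0.23. Of these, 6 of 15 were higher in FRC than in LEC and 1 lower, and 5 of 15 higher in FRC than in BEC and 2 lower. S1pr1 was 18.6-fold higher in LEC and 17.1-fold higher in BEC than in FRC, whereas S1pr3 and the lysophosphatidic acid receptor gene Lpar1 were higher in FRC than in BEC by 20.5-fold (2.99 on the log2 scale through another probe) and 137-fold. Retinoic acid genes had 5 of 11 members higher in FRC than in LEC and 5 of 13 higher in FRC than in BEC (medians -1.71 and -1.08). These included Aldh1a2, which makes retinoic acid (11.4-fold and 31.3-fold), with a LEC minus BEC median of -0.60, which was 0.00978 with no filter on dim probes and -0.12 with the scaling nearest 0.

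Chemokine and cytokine genes divided between the populations: of 38, 5 were higher in LEC than in FRC and 9 lower, 7 higher in BEC than in FRC and 9 lower, and 7 higher in LEC than in BEC and 6 lower, with medians of -0.03, 0.33 and 0.18, the first of which took both signs across the scalings while the last was as low as 0.12. Higher in FRC than in both endothelia were Ccl11 (48.7-fold over LEC and 41.3-fold over BEC) and Tnfsf13b, which encodes the B cell survival factor BAFF (39.5-fold and 66.1-fold, or 3.46 and 5.02 on the log2 scale through another probe). Csf1, the macrophage growth factor gene, was 11.5-fold higher in LEC than in BEC, and Il33 8.38-fold. Csf3, the granulocyte growth factor gene, was 18.5-fold higher in BEC than in LEC. Cxcl12 was 18.4-fold higher in BEC than in LEC through 1 probe, at 6.98 and 2.78, and level between them through another, at 1.02 and 1.10. Both probes were high in FRC, at 6.62 and 6.58. Antigen presentation genes had 3 of 20 members at least 4-fold higher in LEC than in FRC, 1 lower, and 5 of 20 higher in BEC than in FRC, with medians of 1.00 and 1.38, and -0.20 between the endothelia (-0.25 to -0.13 over the scalings). On the same arrays the general leukocyte list had a BEC minus FRC median of 1.998, with 6 of 12 at least 4-fold higher in BEC. Its LEC minus FRC median was 0.80, with 0 of 12 at least 4-fold higher in LEC. The macrophage and dendritic cell list had medians of 1.33 for LEC minus FRC and 0.26 for BEC minus FRC. Cd274, which encodes PD-L1, was 21.2-fold and 18.3-fold higher in LEC and BEC.

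Markers of other cell types that a sort could hold were read in the same way. Of 12 general leukocyte genes, 6 were at least 4-fold higher in BEC than in FRC and 0 in LEC than in FRC. The list had a median of 0.80 in LEC and 1.998 in BEC relative to FRC, and -0.80 for LEC minus BEC. The T and NK cell list had medians of 0.39, 2.12 and -0.79, the B and plasma cell list 0.46, 1.12 and -0.69, and the macrophage and dendritic cell list 1.33, 0.26 and 0.84. Of the T and NK genes 6 of 11 were at least 4-fold higher in BEC than in FRC. The B and plasma cell genes had 4 of 10 higher and 1 lower, and the macrophage genes 0 of 16 higher and 1 lower. Of the macrophage genes, 1 of 16 was at least 4-fold higher in LEC than in FRC and 2 of 16 in LEC than in BEC. With normexp the T and NK medians were 1.10 for BEC minus FRC and -0.09 for LEC minus BEC. The B and plasma cell median for LEC minus BEC was -0.48 with normexp. Both LEC minus BEC values lie inside the random ranges of the main scaling, -0.50 to 0.54 and -0.52 to 0.53. No range was drawn under normexp. The macrophage medians were as low as 0.76, 0.15 and 0.42 over the scalings, in the same order. Erythroid and platelet genes had medians of 2.12, 2.13 (down to 1.39 over the scalings) and -0.66 (-0.72 to -0.32). Without the members given as bounds the last was -1.39. Of 8 members, 4 were higher in LEC and 4 in BEC than in FRC. Of the 10 erythroid and platelet genes on the array, 1 is also in another list. The haemoglobin gene Hba-a1 was at 2.67 in FRC, 5.005 in LEC and 6.55 in BEC. The adipocyte list had medians of 0.00044, 1.64 and -0.98, and Cfd, adipsin, was 32.1-fold higher in BEC than in FRC. The LEC minus FRC median of the adipocyte list took both signs across the scalings. Mesothelial and epithelial genes had 2 of 12 members at least 4-fold higher in FRC than in LEC and 7 of 12 than in BEC. Their medians were -1.02, -2.48 (-3.13 without the members given as bounds) and 1.62 (down to 0.83 over the scalings). Upk3b was 12.9-fold higher in FRC than in BEC. Pericyte and smooth muscle genes had 2 of 16 higher in LEC than in FRC and 5 lower, and 4 of 16 higher in BEC than in FRC and 5 lower, with medians of 0.15, 0.10 (0.06 to 0.13 over the scalings) and -0.95, and Mcam, which endothelium also carries, was 61.4-fold higher in BEC than in FRC. Schwann cell genes had medians of -0.65 (up to -0.11), -1.67 (up to -0.87 over the scalings) and 0.67 (down to 0.36), with S100b 36.5-fold higher in FRC than in BEC.

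Immediate early and dissociation stress genes had a median of 0.29 for LEC minus FRC, 1.12 for BEC minus FRC and -0.77 for LEC minus BEC, with 7 of 29 at least 4-fold higher in BEC than in FRC and 22 between. Over the scalings the first ran from 0.19 to 0.47 and the last from -0.82 to -0.47. Egr3 was 9.81-fold and the heat shock gene Hspa1a 9.54-fold higher in BEC than in FRC. Cell cycle genes had medians of 1.01 for LEC and 1.08 for BEC against FRC and -0.14 between the endothelia (-0.20 to -0.09 over the scalings), but only 2 of 22 were at least 4-fold higher in LEC and 1 of 22 in BEC. Mki67 was 7.27-fold and 11.3-fold higher, or 1.97 and 1.801 on the log2 scale through another probe. Housekeeping genes had medians of 0.03, 0.36 and -0.22, and ribosomal protein genes -0.44, -0.03 and -0.41, all within the middle 95% of random lists. Over the scalings the housekeeping medians ran from 0.00464 to 0.13 for LEC minus FRC and from -0.28 to -0.08 for LEC minus BEC. The ribosomal medians ran from -0.54 to -0.23 for LEC minus FRC, the low end lying below the main-scaling random range of -0.47 to 0.23. They ran from -0.49 to -0.22 for LEC minus BEC, and took both signs for BEC minus FRC. Sex-linked genes had medians of -0.66, -0.89 (up to -0.32 and -0.35 over the scalings) and -0.30, and the first was -1.40 without the members given as bounds. Xist was 6.32-fold lower in BEC than in FRC through its brightest probe. Of its 3 other probes, 1 at 2.06 in FRC also read lower in BEC (-3.12, log2). The other 2, both low at -3.33 in FRC but well above background on all arrays, read higher in BEC (2.37 and 0.96). Besides the lipid droplet list, a list's mean was opposite in sign to its median for LEC minus FRC in the cholesterol synthesis (0.17) and pericyte (-0.73) lists, for BEC minus FRC in the efflux (-0.06) and chemokine (-0.42) lists, and for LEC minus BEC in the fatty acid uptake (-0.15), fatty acid oxidation (0.06), sphingosine-1-phosphate (-0.22) and sex-linked (0.18) lists.

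**Figure D3:**
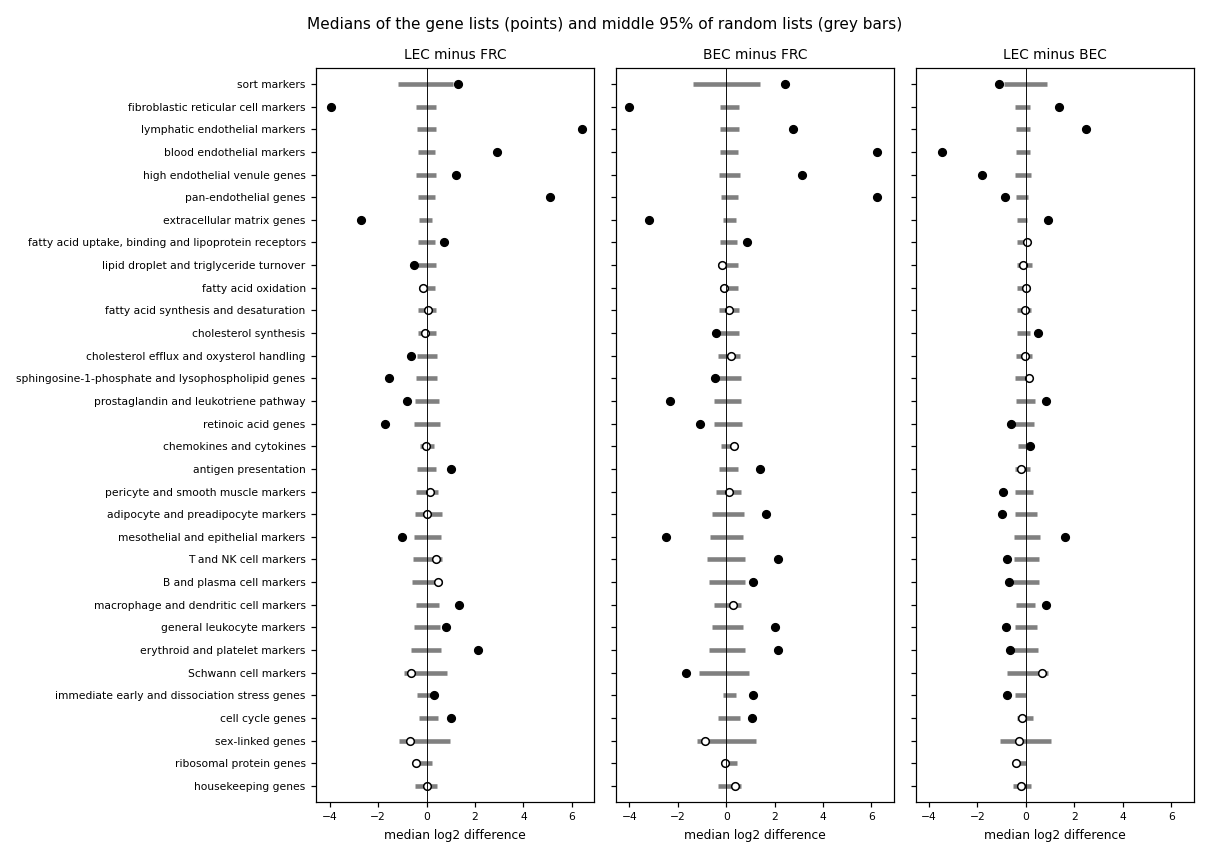
Median log2 difference of each of the 32 gene lists in the 3 comparisons (points), with the middle 95% of 10000 random lists matched on mean expression as grey bars, where filled points lie outside that range and open points inside it. The blood endothelial list lies at 6.24 for BEC minus FRC and -3.47 for LEC minus BEC.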

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

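The counts restricted to agreeing probes, and those without genes whose brightest probe was dim on the lower array, were chosen after seeing the data; the rest were planned. Under quantile normalization, scaling to the median, the series matrix values, the filter on both arrays and the mean of all probes, all 6 counts stayed within 1.5 times their value. So did the counts without genes whose brightest probe was dim. Leaving out saturated probes moved nothing, since none were saturated. In the order LEC over FRC, FRC over LEC, BEC over FRC, FRC over BEC, LEC over BEC and BEC over LEC, the counts of 902, 1094, 1240, 1426, 622 and 620 genes became 550, 636, 740, 854, 287 and 324 with normexp. The offset of 50 added to every signal compresses differences of dim probes by construction. At 2-fold they were 2397, 2459, 3157, 3104, 2009 and 1863, and at 8-fold 449, 583, 631, 748, 201 and 251. Requiring a second measured probe that goes the same way left 270, 332, 349, 435, 185 and 158, since it drops all genes with a single usable probe. With no filter on dim probes, and so with no lower bounds either, LEC over BEC became 1019. Differences of dim probes then count at full size, and which of these changes raised the count was not tested.

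Of 902 genes higher in LEC than FRC, 891 were also called under quantile normalization and 550 under normexp. Of the 562 single differences of at least 4-fold among named and listed genes, all kept their direction under the 4 other scalings, and 469 stayed at least 4-fold with normexp. With the mean of all probes 561 kept their direction, and the exception, Kif11 for LEC minus FRC, gave no difference once bounded. Another probe was measured for 230 of the 562, and was more than 1.5-fold smaller for 97, under 4-fold for 56 and of opposite sign for 12. Of the 96 list medians, 39 moved with normexp, 28 with the mean of all probes, 16 with no filter on dim probes, 13 of those computable with the filter on both arrays, 11 with quantile normalization and 11 with the series matrix values, each by more than the SD estimated from the range of random lists. The median of the retinoic acid genes for LEC minus BEC turned from -0.60 to 0.00978 with no filter on dim probes and no bounds. Which of these changes turned it was not tested. The 75th percentile lay 18.3 to 20.8 times above the lowest signal well above background, so differences of dim genes could only be bounded.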

Other observations

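All tests and the 6 further gene lists in this part were chosen after the data had been seen, and several members of the Wnt and Notch lists had already appeared among the named genes. Of the Wnt genes, 11 of 20 were at least 4-fold higher in FRC than in LEC, 1 lower, and 13 of 20 than in BEC (medians -2.10 and -2.85, and 1.59 for LEC minus BEC, or -1.19, -1.67 and 1.01 with the scaling nearest 0). Without the members given as bounds, the Wnt medians were -2.82 for LEC minus FRC and -4.11 for BEC minus FRC. Rspo1, an R-spondin that amplifies Wnt signalling, was 19.8-fold and 53.9-fold higher in FRC than in LEC and BEC. The Wnt antagonist Dkk2 was 13.3-fold higher in LEC than in BEC. Notch genes had 6 of 18 higher in LEC than in FRC and 3 lower, and 8 of 18 higher in BEC than in FRC and 1 lower (medians 1.03 and 1.58, and -1.41 for LEC minus BEC, up to -0.87 over the scalings). Jag2, a Notch ligand, was at least 20.7-fold and at least 147-fold higher, and Mfng, a glycosyltransferase acting on Notch, was 14.5-fold higher in BEC than in LEC.

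Of the complement genes, 6 of 16 were at least 4-fold lower in BEC than in FRC and 1 higher, and 5 of 15 were lower in BEC than in LEC and 1 higher. The medians were -0.40 (LEC minus FRC), -1.02 (BEC minus FRC, up to -0.61 over the scalings) and 1.35 (LEC minus BEC). C3, the central complement component, was 32.3-fold lower in BEC than in FRC and 10.9-fold lower than in LEC, or 4.23 and 2.71 on the log2 scale through another probe. Hox genes, which mark position along the body axis, differed in direction between members, with 6 of 29 higher in LEC than in FRC and 7 lower, and 7 of 29 higher in BEC than in FRC and 4 lower. Hoxc9 and Hoxc6 were 35.7-fold and 11.8-fold higher in FRC than in LEC, Hoxd10 and Hoxd4 were 15.1-fold and 13.6-fold higher in LEC than in FRC, and Hoxb9 was at least 60.2-fold higher in BEC than in FRC (4.23 on the log2 scale through another probe). The list medians were -0.02, which took both signs across scalings, 0.68 (1.04 without the members given as bounds) and -0.47, the last up to -0.29 over the scalings. Interferon response genes had 3 of 20 at least 4-fold higher in LEC and 5 of 19 in BEC than in FRC, with medians of 0.89, 1.44 and -0.41. The last went down to -0.47 over the scalings, below the main-scaling random range of -0.42 to 0.16. Ifi44 was 19.0-fold and 31.2-fold higher in LEC and BEC than in FRC, and on the same arrays the general leukocyte list had medians of 0.80, 1.998 and -0.80. Toll-like receptor and innate sensing genes had medians of -0.46, 0.05 and -0.25, which ran from -0.49 to -0.29, 0.03 to 0.08 and -0.31 to -0.05 over the scalings.

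Transcripts of each population were also measured on the other arrays, and RNA carried over between sorts is a candidate explanation. If a single share of FRC RNA accounted for all FRC marker and matrix signal on the LEC array, its percent of the FRC signal would be about equal over the 30 members at least 4-fold higher in FRC, but it ran from 1.56% (Pdgfra) to 21.2% (Col8a1), 13.6 times apart. The same ratio was 60.7 for FRC genes on the BEC array, from 0.401% (Pdgfra) to 24.3% (Nid1), 7.64 for lymphatic markers on the BEC array (2.98% for Maf to 22.8% for Fxyd6) and 7.17 for blood endothelial markers on the LEC array (3.17% for Sox17 to 22.7% for Cd300lg), each above the limit of 4 set for a single share. The quartiles of the percents lay closer together, at 2.66% to 8.19%, 1.11% to 5.93%, 6.17% to 17.9% and 4.40% to 10.2%, but without the end members the lowest of the 4 ratios was 6.01, and with the unequal spike-in slopes of the arrays taken out it was 7.99, or 7.41 without the end members. The percents rest on 1 probe per gene, and probes of a gene could differ as widely. Other probes read as low as 2.09 (log2) for Maf and 2.36 for Sox17, so the ratios of the lymphatic and blood endothelial markers decide nothing. Tnxb also varied, at 4.78 and 1.74 for FRC over LEC. Fbln1 read 5.65 and 5.73 over LEC, and Fbn1 2.78 and 2.82. Over BEC they read 6.95 and 7.03, and 4.08 and 3.94. For these FRC genes, a single share as the source of all their signal is argued against. Genes outside these lists set a lower ceiling on any single share than the lowest percents do. Pcolce2 was 82.5-fold higher in FRC than in LEC and 415-fold higher than in BEC. Bmp2 was 92.6-fold higher in LEC than in BEC, and Mycl 160.5-fold higher in BEC than in LEC, each through 1 probe. Mmp9 was at least 142-fold higher in LEC than in BEC, a lower ceiling than that of Bmp2. A smaller share below that ceiling, carry-over of a subset of cells, and low expression by the populations themselves all stay open.

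Of 12 general leukocyte markers, 6 were at least 4-fold higher on the BEC array than on the FRC array (median 1.998), although CD45-bearing cells were removed by magnetic separation and gate. Their lowest median over the 5 scalings was 1.44, above the random range of -0.59 to 0.67 under the main scaling. The result therefore did not depend on which of the 5 was used. The other scalings moved the BEC minus FRC median of all genes by at most 0.0314, too little to test scaling as a cause. Macrophage and dendritic cell genes had a median of 0.26, within their random range of -0.52 to 0.61, and abundant ones such as Lyz2 (-0.35) and Csf1r (0.08) were not raised, which argues against such cells as the whole source. T and B cell lists, none of whose genes is in another list, both lay above their random ranges of -0.78 to 0.79 and -0.70 to 0.76, with the lower median at 1.12 (down to 1.10 for T cell and 0.84 for B cell genes over the scalings), so lymphocyte RNA may contribute: Cd79b was at -0.81 in FRC and 2.79 in BEC, Cd3d at -1.49 and 0.81. Against this, Cd3e (-0.57) and Jchain (-1.94) were not higher in BEC, and expression of leukocyte genes by BEC stays open. Cr2 was lower in BEC, at -5.85 through its brightest probe and 1.54 (log2) toward the same side through another. Its higher FRC signal could hide a lymphocyte share on the BEC array, so Cr2 decides nothing here.

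Immediate early and stress genes had 7 of 29 members at least 4-fold higher on the BEC array than on the FRC array, with the rest between. The median stayed at 1.06 or more over the 5 scalings, above the random range of -0.14 to 0.41 under the main scaling. The scalings moved the BEC minus FRC median of all genes by at most 0.0314, too little to test scaling between arrays as a cause. Handling during the sort cannot be told apart from a difference between the populations, since each population had 1 array. The difference of cell population that the design names was not tested separately.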
